A study of Homo sapiens with 11 samples.

How the data were processed

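RNA was measured in 11 human tumour biopsies, each taken after injection of a radiolabelled form of atezolizumab, an antibody against PD-L1, used as a tracer for positron emission tomography. Per the labels' protocols, RNA came from formalin-fixed, paraffin-embedded tissue (High Pure FFPET RNA Isolation Kit), and libraries were made with the TruSeq RNA Access kit, which enriches coding RNA with capture probes. Reads were demultiplexed with bcl2fastq 2.20 and aligned with GSNAP 2013-10-10 to GRCh38, per the submitters' processing notes. The counting program and the annotation release are not given in the sources used here, nor is whether counting used the strand.

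The authors deposited a table per biopsy with 30727 genes named by Entrez gene ID. Per the file headers, each table holds a raw count per gene, an exonic width in base pairs and an RPKM value. The deposited RPKM values equal the count divided by the width and by a library total that was constant within each file. That total was not the column sum of the counts: the ratio of summed counts to the authors' total was 0.869 to 1.02. The deposited widths were identical in every file and were used as a gene length only in checks. All tests started from the deposited counts, and library sizes were the summed counts of each biopsy. Overlapping genes can each receive the same read, so values of overlapping or near-identical genes are uncertain. Because the capture probes select coding RNA, levels of different genes also depend on the probes, and comparisons were made across biopsies within a gene.

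Gene symbols and coordinates were taken from the RefSeq annotation of GRCh38 through the gene ID, which gave a symbol to 27814 of 30727 IDs (90.5%). The 2913 IDs without a symbol held 0.472% to 1.76% of the counts and stayed in library sizes and tests. Of 294 symbols in 33 gene lists, 289 were matched, 3 of them through an older symbol. HLA-E, HLA-DRA, HLA-DPA1, HLA-DPB1 and UPK3B were not analysed here.

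The labels put all 11 biopsies into 1 group, so no groups were compared, and relations between measures across biopsies took the place of a contrast. Biopsies were numbered 1 to 11 in order. The labels do not say whether any 2 biopsies came from the same patient. The p-values treat the biopsies as independent and would be too small if some shared a patient. The time point field places the biopsies on treatment, whereas the series text places treatment after the scans; the values here do not depend on which holds. No pair of the 55 pairs of biopsies had identical counts, and the lowest chi-square per degree of freedom between any pair was 246.7, far above sampling noise. The labels give no batch.

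Genes were kept if their normalised count (CPM, counts scaled to a common library size) exceeded that of 10 counts in the median library in at least 3 biopsies, which left 19517 genes. Levels are CPM with TMM factors, and log2 CPM used a prior count of 2. A list score is the mean log2 CPM of the members kept. Scores were related to CD274 or to the T effector score by Pearson's r with a two-sided permutation p from 100000 random permutations, the smallest possible p being 1e-05, and by Spearman's rho with its own permutation p. Intervals of r are 95% intervals from Fisher's transformation. Each r was repeated without the 2 biopsies farthest from the median of the x measure, with an exact p over all 362880 orders of the remaining 9. Where a measure had a gap of over 40% of its range with at least 2 biopsies on each side, no r over all biopsies was computed, and r was given only within a cluster of at least 6. Members of the T effector list were taken out of the lists related to it, and CD274 out of the lists related to CD274.

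Genome-wide relations were fitted with the quasi-likelihood test of edgeR 4.0.16 (robust) on the counts, with an intercept and CD274 log2 CPM or the T effector score as covariate. Slopes are log2 changes per unit of the covariate, and p-values were adjusted by the Benjamini-Hochberg method within each family at 0.05. The SE given with a slope of these fits is the absolute slope divided by the square root of the test's F statistic. It was not estimated separately and restates that F. Lists were tested against other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. DESeq2 1.42.0 and limma-voom were alternatives. R 4.3.3 was used, with Python for tables and plots. The code was tested on simulated counts with the biopsies' own means, library sizes and covariates. Over 19192 genes, the T effector fit recovered 67.0% of 100 genes with a true slope of 1 and 5.0% of 100 genes with a slope of 0.5 per unit. Over 19247 genes, the CD274 fit recovered 38.0% and 6.0% at these slopes. The share of false calls was 1.37% and 2.22%. Simulated genes were drawn independently of each other, and true slopes were placed only on genes above a minimum mean count. Real genes vary together, so these shares need not hold in the biopsies. Among 1000 pairs of unrelated measures, 4.7% had a permutation p under 0.05.

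The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. Genes named are members of the fixed lists, the 20 genes with the highest SD of log2 CPM among those with a mean log2 CPM of at least 3, and, for each genome-wide fit, the 10 genes of each sign with the smallest p among those past the threshold whose Spearman rho and whose slope without the 2 farthest biopsies had the same sign. Where no gene passed, the 5 of each sign with the smallest p are given as values only. Outside this rule, MALAT1 is named for its share of the counts. Further genes associated with the T effector score, named among the other observations, were picked after their values were seen. Of the lists, 20 were tested and 13 were described only. Genes that could help identify a person, including genes on the Y chromosome and variable segments of antigen receptors, were not named. Alternatives were other normalizations, prior counts and scores, Spearman's rho, partial correlations given depth or the epithelial cell score, other count models, no low-count filter, ranks of the covariate, and leaving out each biopsy or the 2 farthest. Leaving out biopsies 5, 7 and 11 together was added after the data were seen.

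Totals were 16410512 to 67016339 counts per biopsy, so that 3 counts, the floor below which a gene is not told from 0, correspond to 0.0448 to 0.183 CPM. Counting errors and floors cover sampling of reads only, and intervals of r and of slopes cover the spread between biopsies.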

Results

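RNA from 11 tumour biopsies was profiled by exome-capture sequencing. The biopsies followed a PET scan with labelled atezolizumab, an antibody that blocks PD-L1 and with which the patients of the trial were treated. PD-L1, the product of CD274, is a ligand that restrains T cells through the receptor PD-1 (PDCD1). The labels give a single group, without tumour type, tracer uptake or outcome, so the values describe how the biopsies differed from each other. Total counts had a median of 39475272, from 16410512 in biopsy 7 to 67016339 in biopsy 6. Between 16447 and 19217 genes had at least 10 counts. Biopsy 7 also had the lowest share of counts in small RNA genes, 0.378%, against up to 2.73% in the others. MALAT1, an abundant nuclear RNA, held 1.23% to 5.89% of the counts.

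CD274 (GRCh38 chromosome 9, 5450542 to 5470554) was detected in all 11 biopsies, with 102 to 1107 counts. Its level was 12.3 CPM ± 10.3 (SD, n = 11) and spanned from 1.62 CPM in biopsy 6 and 2.32 CPM in biopsy 5 to 27.7 CPM in biopsy 8 and 33.3 CPM in biopsy 7. On the log2 scale its SD was 1.36, larger than that of 92.4% of the 10546 genes with a mean log2 CPM of at least 3. The counting error of CD274 was 0.04 to 0.14 log2 units in any biopsy. PDCD1LG2, which encodes the other PD-1 ligand and lies beside CD274 at 5510531 to 5571282, had 10.7 CPM ± 6.60 (SD, n = 11).

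The receptors of exhausted and activated T cells were found at a few CPM. PDCD1 had 3.09 CPM ± 3.33 (SD, n = 11), TIGIT 1.63 CPM ± 1.76, CTLA4 5.76 CPM ± 5.72, LAG3 7.70 CPM ± 12.1 and the costimulatory receptors ICOS and TNFRSF9 6.00 CPM ± 4.86 and 2.40 CPM ± 2.02. HAVCR2, which encodes TIM-3, a receptor of T cells and myeloid cells, had 13.5 CPM ± 10.2. The B7 family members CD276 and VTCN1 differed in their spread. CD276 (B7-H3) was at or above 18.6 CPM in each biopsy, with a mean of 37.4 CPM ± 16.3, whereas VTCN1 (B7-H4) ranged from 0 counts to 47.9 CPM and exceeded 1 CPM in 7 of 11 biopsies. IDO1, an interferon-induced enzyme of tryptophan breakdown, ranged from 1.95 to 125 CPM.

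**Figure D1:**
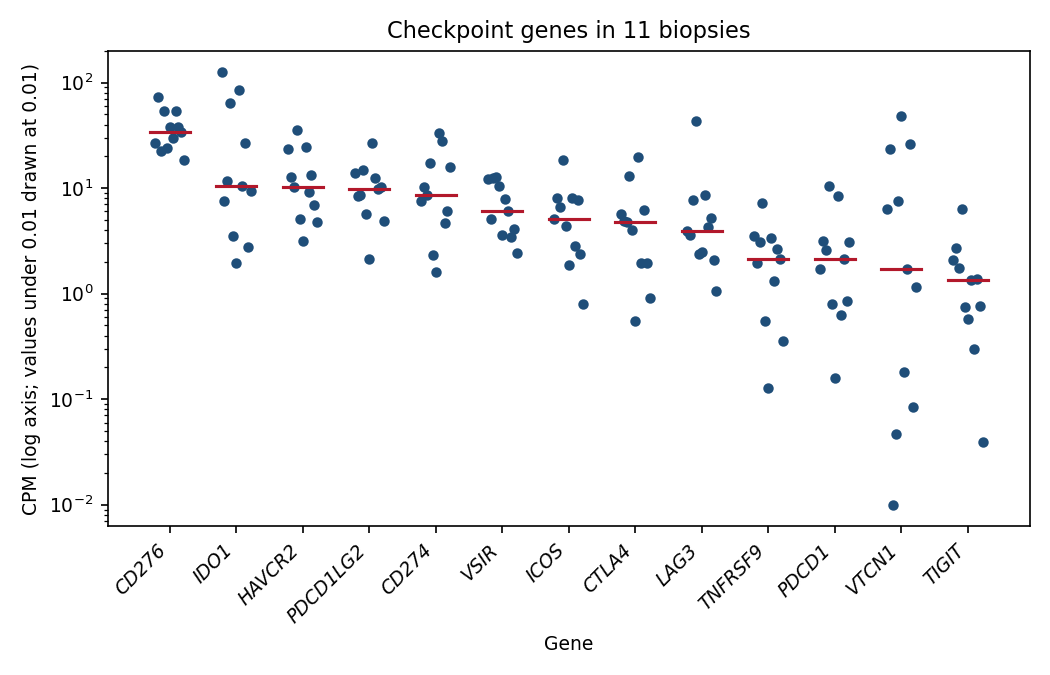
Levels of 13 checkpoint genes in 11 biopsies as CPM on a log axis, where each point is a biopsy and each red line the median over biopsies. The median of CD276 was 34.1 CPM, and VTCN1 ranged from 0 counts to 47.9 CPM.

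The T effector list holds CD8A, GZMA, GZMB, IFNG, EOMES, CXCL9, CXCL10 and TBX21, genes of cytotoxic T cells and of the chemokines that attract them, and has served as an RNA biomarker in atezolizumab trials. Its score ranged from -0.46 in biopsy 6 to 5.30 in biopsy 4, with a median of 2.93. The cytotoxic T cell receptor component CD8A ranged from 2.30 to 141 CPM, the protease GZMB from 0.697 to 57.4 CPM and the chemokine CXCL9 from 0.681 to 266 CPM. IFNG, which encodes interferon gamma, had 0.576 CPM at the median and at least 4 counts in each biopsy.

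Most checkpoint genes and several immune lists tracked the T effector score across biopsies. Of 31 measures tested, 16 passed an adjusted permutation p of 0.05, and all 16 were positive (n = 11). Among the checkpoint genes, 9 of 13 did so. HAVCR2 had r = 0.943 (p = 1e-05, the smallest the permutations can give, adjusted p = 0.000207; rho = 0.955), TNFRSF9 r = 0.932, CTLA4 r = 0.913, ICOS r = 0.911, LAG3 r = 0.849, TIGIT r = 0.827, PDCD1 r = 0.817, PDCD1LG2 r = 0.778 and IDO1 r = 0.752 (adjusted p = 0.0154). Of the lists, 7 of 18 passed. The interferon gamma response list, genes such as GBP1 that the cytokine induces, had r = 0.940 (p = 2e-05, adjusted p = 0.000207; rho = 0.936). The T effector score holds IFNG itself, so score and list are not independent measures. IDO1 enters the 16 both alone and as a member of this list. The T cell list had r = 0.915, MHC class II presentation 0.90, NK cells 0.858, regulatory T cells 0.855, macrophages 0.836 and MHC class I presentation 0.809 (adjusted p = 0.00667). By Spearman's rho, 17 measures passed, the B cell list being the added one.

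Other measures did not pass. CD274 itself was among them (adjusted p = 0.186), as were VSIR (r = 0.630, adjusted p = 0.0621), CD276 (r = 0.337) and VTCN1, whose r was -0.414. Plasma cells (r = 0.660, adjusted p = 0.0508) and B cells (r = 0.632, adjusted p = 0.0621) lay just outside the threshold, type I interferon response had r = 0.572 and dendritic cells 0.477. For neutrophils r was 0.299. For stromal and tumour programmes, r was 0.30 for fibroblast and matrix genes, 0.292 for the fibroblast TGF-beta response, 0.165 for proliferation, 0.057 for endothelial cells, 0.042 for the 9p24 neighbours of CD274 and -0.301 for hypoxia and glycolysis. The adjusted p was 0.425 or more in each of these and for neutrophils. The 95% intervals of these r values were wide, from -0.562 to 0.635 for endothelial cells. Without biopsies 6 and 11, which lay farthest from the median score, all 16 passing measures kept their sign and 11 stayed past the adjusted threshold by exact permutation. PDCD1LG2 fell to r = 0.493 (adjusted exact p = 0.302), macrophages to 0.661 (0.106), and regulatory T cells to 0.713, NK cells to 0.728 and IDO1 to 0.712 (each 0.0667). PDCD1LG2 (adjusted p = 0.0799) and IDO1 (adjusted p = 0.0608) also lost their calls without biopsy 6 alone, and MHC class I presentation (adjusted p = 0.0527) without biopsy 4, by permutation.

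**Figure D2:**
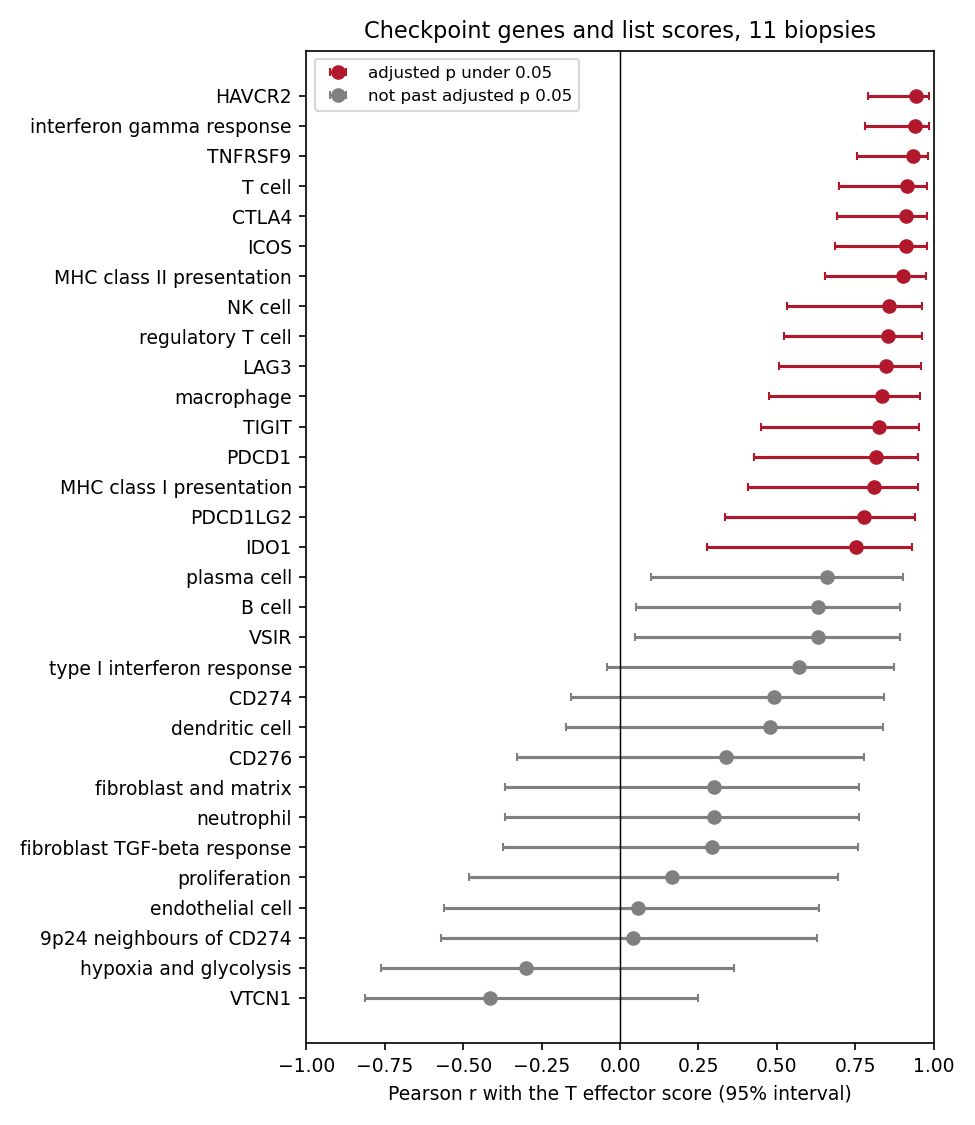
Pearson r with the T effector score for 31 checkpoint genes and list scores over 11 biopsies, with 95% intervals as bars. The 16 measures with adjusted p under 0.05, in red, range from 0.752 for IDO1 to 0.943 for HAVCR2.

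The epithelial cell score fell into separate clusters, 6 biopsies at 6.15 to 6.41 and 5 biopsies at 7.51 to 8.17, so no r over all biopsies was computed. Biopsies 8 and 10 had the highest basal and squamous scores (9.43 and 8.03) but lay in the lower cluster. KRT7, a member of the epithelial list, had 4.52 and 2.38 CPM in them. The epithelial score thus need not follow the share of squamous epithelium. Within the 6 biopsies of the lower cluster, r was -0.677 with the T effector score (exact permutation p = 0.156) and -0.242 with CD274 (exact permutation p = 0.786).

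Gene by gene, 135 of 19509 genes were associated with the T effector score at an adjusted p of 0.05 in edgeR's quasi-likelihood test, 131 with a positive slope and 4 with a negative one. The interleukin receptor chain IL2RB, used by T and NK cells, had the smallest p, with a slope of 0.91 ± 0.09 (SE) log2 units per unit of score (adjusted p = 0.00914) and levels from 1.30 to 34.3 CPM. Cytotoxic and homing genes rose with it: the T cell chemokine CCL5 (slope 0.88 ± 0.11), the granzyme GZMH (1.01 ± 0.13), the death ligand FASLG (1.02 ± 0.14) and ITGAE (0.69 ± 0.09), the integrin chain of tissue-resident T cells. CIITA, the master activator of MHC class II genes, rose with slope 0.64 ± 0.07 and ranged from 42.5 to 405 CPM, and the interferon-induced GTPases GBP5 and GBP1 rose with slopes of 1.07 ± 0.14 and 0.79 ± 0.11. FCRL3, a receptor of lymphocytes, and MYO7A, an unconventional myosin, completed the 10 genes with the smallest p, with slopes of 1.23 ± 0.17 and 0.84 ± 0.09. On the negative side, CCT8, a subunit of the cytosolic chaperonin, fell with slope -0.39 ± 0.07 (adjusted p = 0.0427) and SERHL with -0.89 ± 0.18 (adjusted p = 0.0498). CTAGE9 (slope -1.80 ± 0.34) had an r of only -0.556 (permutation p = 0.0884). Without biopsies 6 and 11 the slopes were -0.26 for CCT8 (exact p of r = 0.0269), -0.32 for SERHL (exact p = 0.107) and -0.48 for CTAGE9 (exact p = 0.322). CTAGE9 and SERHL have close paralogs, so their counts are uncertain.

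For the T cell list 8 of 10 members passed over all genes, and 10 of 10 adjusted over the list alone. CD2 had a slope of 0.95 ± 0.15, CD3D 0.89 ± 0.12, CD3E 0.79 ± 0.12 and LCK 0.75 ± 0.12. For the interferon gamma response 6 of 12 passed over all genes and 12 of 12 adjusted over the list alone, among them UBD (1.01 ± 0.17) and TAP1 (0.59 ± 0.12). Of the macrophage genes 3 of 10 passed, 8 adjusted over the list alone, C1QC having a slope of 0.58 ± 0.10. NK cell genes passed in 3 of 8 cases, 4 adjusted over the list alone: GNLY, KLRD1 and NKG7, which cytotoxic T cells also express. MHC class II presentation had 2 of 5 (5 adjusted over the list alone), including CD74 at 0.53 ± 0.10, MHC class I presentation 2 of 7 (4 adjusted over the list alone), including NLRC5 at 0.54 ± 0.10, and the checkpoint genes 5 of 13 (9 adjusted over the list alone). No member passed over all genes in the regulatory T cell list (2 adjusted over the list alone), the type I interferon list (1 of 10 adjusted over the list alone), or the B cell, plasma cell, neutrophil, dendritic cell, fibroblast, endothelial, proliferation, hypoxia, epithelial and 9p24 lists (0 adjusted over the list alone). B cell genes had the median slope of 1.14 with all 8 members positive, and MS4A1 an adjusted p of 0.339.

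Against other genes, camera placed 14 of 19 lists past an adjusted p of 0.05, 12 upward and 2 downward. With an estimated correlation 7 held: T cell and interferon gamma response (adjusted p = 0.00595 for both), NK cell (0.00784), MHC class II (0.0195), macrophage (0.0207), regulatory T cell (0.0244) and MHC class I presentation (0.0444). The others did not, with an adjusted p with an estimated correlation of 0.0585 for the epithelial list, which was downward, 0.166 for plasma cells, 0.169 for B cells, 0.177 for type I interferon, 0.335 for dendritic cells, 0.481 for hypoxia and glycolysis, also downward, and 0.507 for fibroblast and matrix genes. The number of single genes rested on few biopsies. It was 0 without biopsy 4, 2 without biopsy 6, 34 without biopsy 11, 40 without biopsy 7, 60 without biopsy 9, 67 without biopsy 3, 71 without biopsy 1, 71 without biopsy 8 and 73 without biopsy 10, and it was 0 with the epithelial cell score and 23 with log2 total count as a second covariate. The median slope of the 131 positive genes did not shrink without biopsy 4 (0.75) or biopsy 6 (0.74), against 0.71 with all, while its median SE rose from 0.12 to 0.16 and 0.15. These genes were chosen by their slopes over all biopsies, and the refits share most of those biopsies, so the kept slope is no independent support.

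The relation of CD274 to the T effector score did not pass the threshold. The correlation was r = 0.490 (permutation p = 0.123, adjusted p = 0.650; rho = 0.591, p = 0.0599), with a 95% interval of -0.155 to 0.842. Without biopsies 6 and 7, the lowest and highest in CD274, r fell to 0.138 (exact p = 0.729), but this removal also narrows the range of CD274. Without biopsies 6 and 11, farthest from the median T effector score, r was 0.414 (exact p = 0.269). Leaving out any 1 biopsy gave 0.237 to 0.635. Biopsy 8, with 27.7 CPM of CD274, had a T effector score of 1.57, and biopsy 11, with 15.7 CPM, a score of 0.46, whereas biopsy 9 had 4.65 CPM and a score of 2.93. Of 19 list scores related to CD274, none passed the adjusted threshold by r or by rho, and 1 had an unadjusted p under 0.05: MHC class I presentation, with r = 0.609 (permutation p = 0.0447; rho = 0.518, p = 0.108), which was 0.447 (exact p = 0.225) without biopsies 6 and 7. Interferon gamma response had r = 0.547, macrophages 0.437, MHC class II 0.397, hypoxia and glycolysis 0.362, NK cells 0.330, the fibroblast TGF-beta response 0.319, regulatory T cells 0.316, T cells 0.187, proliferation 0.159, B cells 0.145, plasma cells 0.113, fibroblast and matrix genes 0.060, neutrophils -0.054, type I interferon response -0.082, dendritic cells -0.089 and endothelial cells -0.405. Genes next to CD274 on 9p24, such as JAK2 and PLGRKT, had r = 0.106 as a list (95% interval -0.527 to 0.664).

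**Figure D3:**
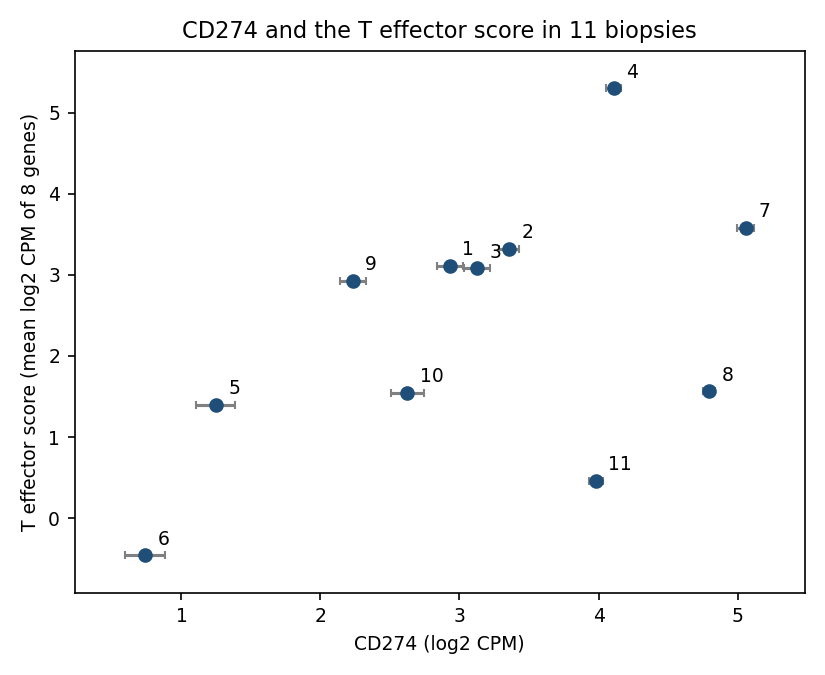
CD274 (log2 CPM, horizontal bars are the counting SD) against the T effector score in 11 biopsies, numbered by biopsy. Biopsies 8 and 11 pair high CD274 with low scores, and r over all 11 is 0.490.

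No gene of 19516 was associated with CD274 at an adjusted p of 0.05 in edgeR's quasi-likelihood test or in limma-voom, while 1736 had an unadjusted p under 0.05 in edgeR and DESeq2's Wald test called 250. The smallest adjusted p was 0.0767, for SPMIP5, a gene with at most 1.81 CPM. As values only, the positive slopes with the smallest p were those of RBL1, a relative of the retinoblastoma protein (0.46 ± 0.09 SE; 13.7 to 67.9 CPM), the lactate exporter SLC16A3 (0.86 ± 0.18), the adenosine receptor ADORA2B (0.92 ± 0.19), the adenylate cyclase ADCY7 (0.53 ± 0.11) and LCE1F, which did not exceed 0.727 CPM. Negative slopes were those of SPMIP5, OR9A2 (up to 9.60 CPM), the zinc finger gene ZNF737 (-1.15 ± 0.18; 10.3 to 1536 CPM), the transporter ABCC11 (-2.45 ± 0.41; 0.182 to 750 CPM; -1.14 without biopsies 6 and 7, exact p of r = 0.234) and SNORD115-1 (up to 1.22 CPM). ZNF737 belongs to a family of similar zinc finger genes and its counts are uncertain. Its adjusted p was 0.137 over all biopsies and 0.00622 in edgeR without biopsy 7, the only removal of a single biopsy that gave any call. Among members of fixed lists, adjusted over the list alone, 3 regulatory T cell genes (2 positive, 1 negative) and 2 checkpoint genes passed, and 0 in the other immune lists. With the preset correlation, camera placed 11 of 20 lists past the threshold for CD274, 9 upward, led by the interferon gamma response (adjusted p = 1.08e-06), the T effector list and MHC class I presentation (both 0.00015), and 2 downward, epithelial and endothelial cells. None held with an estimated correlation, where the adjusted p was 0.519 or more.

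The median SD of log2 CPM was 0.61 over 10546 genes, against a median counting SD of 0.04, and 208 genes had an SD over 2. The first principal component of these genes held 22.3% of the variance. Its r was 0.731 with the share of small RNA genes and 0.238 with log2 total count. The second held 16.8%, with r = 0.031 and -0.677 for the same measures. No p was computed, and a technical part of this spread is not excluded. The 20 most variable genes are listed by kind as read from their names, without a test of any kind against the rest, and 6 of them stayed among the top 20 at a minimum mean log2 CPM of 5: KRT6A, KRT17, CPS1, CEACAM5, MUC6 and MUC4. The desmosomal cadherin DSC3 had an SD of 4.78 and ranged from 0.0775 to 1252 CPM, the basal keratin KRT5 an SD of 4.63 with up to 9093 CPM, and KRT6A, KRT6B, KRT6C, KRT16 and KRT17 SDs of 3.87 to 4.42, though these keratins share reads with close paralogs. CLCA2 had an SD of 4.46 and FAM83B 3.73. The phosphate transporter SLC34A2 ranked second (4.64), and the secretory or surface genes included the mucins MUC5AC (3.98), MUC6 (3.74) and MUC4 (3.71), CEACAM5 (3.83) and the lipocalin APOD (3.70). The mitochondrial urea cycle enzyme CPS1 had an SD of 4.06 and up to 4222 CPM. FREM2 had an SD of 4.43 and AKR1C2, which has close paralogs, 4.24. MIR650 (4.08), which lies within the immunoglobulin lambda locus, and the plasma cell receptor FCRL5 (3.64) were the lymphoid entries.

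Several genes of the lineage lists were high in few biopsies, while others were not. TTN, of the skeletal muscle list, exceeded 100 CPM in 11 of 11 biopsies. The urothelial list members PPARG and GATA3 exceeded 10 CPM in 9 and 8. TP63, a transcription factor of basal and squamous cells, exceeded 100 CPM in 4 biopsies, and KRT5 in 3. The surfactant gene SFTPB exceeded 100 CPM in 2 biopsies (3 and 6) and NAPSA, an aspartic protease of lung epithelium, in 2 (3 and 7). The urothelial gene UPK2 exceeded 100 CPM in 1 biopsy (5), as did the mammary gene SCGB2A2 (6), and the mammary antigen ANKRD30A in 2 (6 and 9). CHGA, a marker of neuroendocrine cells, reached 59.3 CPM in 1 biopsy and stayed at or below 10 CPM in the others. Skeletal muscle genes were high in biopsy 11, with MYH2 at 1669 CPM against a median of 1.56 CPM, and hemoglobin genes held 1.89% of the counts of biopsy 5 against a median of 0.013%. ALB reached 2127 CPM in 1 biopsy (6) although APOA1, another hepatocyte gene, did not exceed 0.133 CPM in any. Biopsy 6, with the lowest CD274 and the lowest T effector score, thus held mammary, surfactant and ALB signal together.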

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

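Leaving out biopsies 5, 7 and 11 together was the one alternative chosen after the data were seen. The count of 16 measures correlated with the T effector score was 11 to 19 under every alternative run, and the 0 list scores correlated with CD274 stayed at 0 in all of them. Leaving out each biopsy in turn gave 15 to 18 and 0. The mean log2 CPM of CD274 was 3.11 and became 3.10 with a prior count of 0.5, and the median SD of log2 CPM was 0.61, against 0.55 at a higher minimum level and 0.71 from edgeR's biological variation. The 16 single correlations kept their sign in all 352 values and fell below the threshold in 15, and CD274 with macrophages turned to r = -0.109 given the epithelial cell score (r = 0.437 without it, neither past the threshold); the cause was not tested. The 135 genes associated with the T effector score became 835 in DESeq2's Wald test (618 positive and 217 negative, including all 135), 213 in limma-voom (132 shared), 23 with log2 total count as a second covariate and 0 with the epithelial cell score as one. Without a low-count filter there were 137, of which 23 had negative slopes. The count was 0 without the 2 farthest biopsies and 0 without biopsies 5, 7 and 11, and leaving out each biopsy gave 0 (without biopsy 4) to 105 (without biopsy 2). Fewer samples or residual degrees of freedom enter these fits, but the cause was not tested. The median slope of the 131 positive genes moved little, from 0.71 to 0.66 with either second covariate and to 0.66 without the 2 farthest biopsies. As the genes were chosen by their slopes in the main fit, this is no independent support. For CD274 the 0 genes became 250 in DESeq2, 12 without a low-count filter, 1 with the epithelial cell score, 1 with ranks of CD274, and 0 to 1 on leaving out each biopsy, 1 being reached without biopsy 7; the cause was not tested. The 11 lists that camera called for CD274 became 0 with an estimated correlation and 4 without the 2 farthest biopsies, of which 2 were among the 11, and the 14 for the T effector score became 7 and 12, all among the 14; the cause was not tested. The estimated correlation was 0.728 for the interferon gamma response with CD274 and -0.00669 for regulatory T cells with the T effector score, against a preset of 0.01. TIGIT, with as few as 2 counts, and VTCN1, with as few as 0, reached lower counts than CD274, with at least 102, so their lowest levels are less certain. With 11 biopsies, 38.0% of simulated genes with a slope of 1 on CD274 were recovered.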

Other observations

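Tests of scaling and epithelial share for the T effector relations, of counting error for CD274, of the stress list and of chance for CD274, and the removal of single biopsies from the lineage lists, were chosen after the result was seen, as was the use of a planned correction for total count to weigh depth. Of the 133 named genes associated with the T effector score, 103 belonged to no fixed list, and the examples here were chosen after their values were seen. They included further cytotoxic T cell genes, such as perforin (PRF1, slope 0.92), the signalling kinase ZAP70 (0.85) and the shared cytokine receptor chain IL2RG (0.90). Myeloid genes were also among them, namely the Fc receptor FCGR3A (0.76), the oxidase subunit CYBB (0.65), the endosomal receptor TLR8 (0.76) and SIGLEC1 (0.58). So were the cytokines IL15 (0.76), TNF (0.88) and LTB (0.95). CXCL13, a chemokine that attracts B cells and is made by exhausted T cells in tumours, had a slope of 1.12 ± 0.20 (SE, adjusted p = 0.0356 in edgeR) and was the only member of the lymph node list to pass, while 8 of 8 B cell genes had positive slopes of which none passed.

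Urothelial, erythroid and mammary genes, from lists that were described only, mostly had negative slopes on CD274, but 0 of them passed over all genes in edgeR. Adjusted over the list alone, 7 of 8 urothelial, 5 of 6 erythroid and 5 of 7 mammary genes passed with negative slopes, with 1 mammary gene positive. The urothelial score was 7.79 in biopsy 5 and at most 3.13 in the others, and without biopsy 5 (2.32 CPM of CD274) 1 of 8 urothelial and 0 of 5 erythroid genes passed. The urothelial count was also 3 without biopsies 1, 4, 8 or 11 and 4 without biopsy 10. Without biopsy 6 (1.62 CPM), 0 of 6 mammary genes passed, and 3 passed with negative slopes without biopsies 4 or 7. The positive mammary call was lost without biopsy 1, 2, 4, 6, 7 or 9. Skeletal muscle genes had 8 of 8 positive slopes on CD274, none passing, and 0 of 8 positive slopes on the T effector score, where 6 passed over the list alone. Without biopsy 11, which holds most of the muscle signal, 3 of 7 and 5 of 7 slopes were positive and 0 passed, and the 6 became 2 without biopsies 1 or 3 and 0 without biopsy 2. On the T effector score 3 of 7 mammary genes also passed with negative slopes, 0 without biopsy 6 and 5 without biopsy 9, and 2 of 8 hepatocyte genes, 1 without biopsies 5 or 11 and 0 without biopsy 6. Mean list scores were 0.34 ± 1.36 (SD, n = 11) for adipocytes, 0.87 ± 1.17 for mesothelium and -0.24 ± 1.18 for neuroendocrine cells, and the lymph node stroma and follicle score ranged from -2.27 to 2.71.

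For the joint rise of checkpoint genes and immune lists with the T effector score, 16 of the 16 called measures stayed past the threshold given log2 total count. This argues against a linear effect of depth for these measures. The score itself had r = -0.470 with log2 total count (permutation p = 0.145). For single genes the question stays open, as 135 became 23 with that covariate, though the median slope of the 131 positive genes moved only from 0.71 to 0.66. A scaling factor shared by all genes cancels in a difference of scores, yet 13 of the 16 measures rose against endothelial genes and the same 13 against proliferation genes. The r of these references with the T effector score, 0.057 and 0.165, was known when they were chosen. Their differences therefore mostly restate the single r values. Against fibroblast genes, the most variable of the 3 references, all 16 slopes stayed positive (median 0.51; 0.65 for T cells, 95% interval 0.16 to 1.13) with 0 calls when adjusted within that reference. Adjusted over the 3 references together, IDO1 (adjusted permutation p = 0.0196), the interferon gamma response (0.0362), T cells and TNFRSF9 (both 0.0474) passed against fibroblast genes, and the other measures did not. Such a factor is thus argued against for the 13 and stays open for 3, PDCD1LG2, regulatory T cells and MHC class I presentation. A lower share of epithelial cells would raise other cell types alike, yet the T cell score rose above the endothelial score with a slope of 0.82 (95% interval 0.64 to 1.00, permutation p = 2e-05). This slope restates that r with the T effector score was 0.915 for T cells and 0.057 for endothelial cells. Its p is no evidence beyond those r values. Given the score of lymph node genes 16 of the 16 measures passed. These values argue against lymph node tissue for all 16 and, judged by the endothelial list, against epithelial share for the T cell list. Given the epithelial cell score 13 passed and MHC class I presentation (r = 0.652, adjusted permutation p = 0.0621), PDCD1LG2 (0.585, 0.111) and IDO1 (0.607, 0.0945) did not, so for these 3 epithelial share stays open. The epithelial cell score fell into separate clusters, so passing a linear correction for it does not by itself clear the 13. It was also low in biopsies 8 and 10 (6.33 and 6.41), which had the highest basal and squamous scores. A correction for it may therefore follow tumour lineage as well as epithelial share. With the epithelial cell score in edgeR's fit 0 genes passed (1552 at an unadjusted p under 0.05). The median SE of the 131 positive genes, which were chosen in the fit without that score, rose from 0.12 to 0.16 while their median slope went from 0.71 to 0.66. Of 100 assignments of the scores to the biopsies, only the real one gave 135 genes or more (1 of 100), the highest of the others giving 12. By an unplanned count of genes at an unadjusted p under 0.05 in edgeR, 3 of 100, the real one included, reached the real 2091 (highest other 2370). Both argue against a chance assignment of scores. The score comes from the same libraries as the genes, so neither says why they vary together. The count of 135 was nonetheless 0 without biopsy 4 and 2 without biopsy 6. Beyond lymph node tissue and epithelial share, no biological explanation was tested for this rise.

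By correlation of scores CD274 passed with no immune list, although camera at its preset correlation called 11 of 20 lists and with an estimated correlation 0. Counting error made 0.476% of the variance of CD274, which argues against counting noise alone, but of 12 relations to technical measures the largest was that of CD274 with the number of genes with at least 10 counts (r = -0.614, permutation p = 0.0439, adjusted p = 0.291; rho = -0.527), so other effects of depth or complexity stay open. After the T effector score was fitted, CD274 fell into separate clusters, 8 biopsies at least 0.15 log2 units below the fit and biopsies 7, 8 and 11 at least 1.44 above it, so r could be taken only within the 8 (0.166 with basal and squamous genes, exact permutation p = 0.674, rho = 0.190; 0.361 with hypoxia and glycolysis, exact permutation p = 0.446, rho = 0.357), which leaves out the 3 to be explained and decides nothing. Those 3 had hypoxia and glycolysis scores of at least 7.05, above all others (at most 6.32) except biopsy 10 (8.48), and basal and squamous scores of 1.10, 9.43 and 0.79. Both explanations thus stay open, and no other biological explanation was tested. With a real count of 0 adjusted genes all 100 of 100 assignments of CD274 gave as many (highest other 2), which says nothing about chance, whereas 9 of 100 gave as many genes at an unadjusted p under 0.05 as the real 1736 (highest other 2242), so chance is not excluded there.

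The immediate early and stress list, which includes FOS, EGR1 and HSPA1A, had scores of 3.15 to 6.47, and FOS ranged from 7.93 to 391 CPM. Handling of the tissue before fixation is a candidate cause that no label records. The score had r = -0.038 with log2 total count (permutation p = 0.913), 0.246 with the log2 share of small RNA genes (permutation p = 0.489; rho = 0.482) and 0.544 with the hypoxia and glycolysis score (permutation p = 0.0799; rho = 0.545), all over 11 biopsies. Without the 2 biopsies farthest from the median of the second measure, r rose to 0.780 for small RNA and fell to 0.319 for hypoxia, so both relations hung on few biopsies. With 11 biopsies these intervals span more than 0.5 on some side, so depth, RNA quality and hypoxia could not be excluded, and no other explanation was tested.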
